A study of Dendrobium catenatum with 16 samples.

How the data were processed

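RNA sequencing of poly(A) messenger RNA was available for 16 libraries from aerial tissue (young leaves, stems and shoots) of cultured Dendrobium catenatum plantlets. The first experiment had 8 libraries in 4 groups of 2 (distilled water, NAA at 0.1 mg/L, 6-BA at 1.0 mg/L and both hormones, 3 weeks, plantlets 2 months old). The second had 8 single libraries (none or 6-BA at 0.5, at 1.0 or at 2.0 mg/L, 2 and 4 weeks, plantlets 9 months old). Samples were grouped by the hormone, dose and time that the labels state, and no library was left out of the fits.

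Per the submitters' processing notes, reads were handled with HISAT2 2.0.6, Cufflinks 2.2.2 and edgeR (version not given), and the notes do not say which tool gave which table. The deposited tables of each experiment hold a count per gene and library in raw counts. Per the file headers, the authors' tables also hold FPKM, with the gene length and the position of each gene in bases. The genome build, the annotation release and the strandedness of the libraries are not given in the sources used here. The count tables held 23063 features in the first experiment and 28537 in the second, of which 26185 carry gene numbers and 2352 are loci without one. A total of 22701 genes of the first table were named in the second by gene number. FPKM of the first experiment were scaled by the library totals, and those of the second by another effective library size. No column belonged to a sample outside these 16 (columns_of_other_samples 0). Gene descriptions and positions came from the authors' tables, and 26064 gene numbers of the second table were also found in a RefSeq gene table.

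Total counts were 34.3 to 74.5 per library in units of 1e6 in the first experiment and 15.1 to 16.3 in the second. The biological coefficient of variation was 0.115 for the first experiment with 4 groups and 0.122 for its additive model, and 0.499 (any dose) and 0.518 (dose slope) for the second, where it includes misfit of the additive model.

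Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and plots in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9. Genes with low counts were removed with filterByExpr, libraries were scaled by TMM, and edgeR's quasi-likelihood test was used with Benjamini-Hochberg adjustment at 0.05. In total 19420 genes were tested with the 4-group model, 19303 with the additive model of NAA and 6-BA, and 21267 in the second experiment. The first experiment was compared as NAA, 6-BA and both against water, as their interaction, and as each hormone averaged over the other. The second was fitted with week plus 6-BA at any dose, and with week plus dose, and single doses were set against 0 mg/L of the same week without a test. Levels in the text are CPM (counts scaled to a library total of 1e6). They come from TMM-scaled library sizes in the first experiment and from the library totals in the second. Standard errors are model-based.

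Gene lists were drawn from words in the gene descriptions before the data were examined: beta-glucosidase, mannan and glucomannan synthesis, cellulose synthase, sucrose and starch metabolism, cell wall loosening and hydrolysis, sugar transport, mannose-binding lectin, cytokinin response and turnover, auxin response, other hormone response, photosynthesis, chlorophyll synthesis, cell division, histone, phenylpropanoid and lignin, flavonoid synthesis, terpenoid and sterol backbone, alkaloid-related, heat shock and chaperone, defence and chitinase, nitrate and nitrogen, shoot meristem and leaf patterning, root tissue markers, floral organ markers, ribosomal protein, and chloroplast-encoded and organelle transcripts. Word matching takes in some neighbours: the sucrose list holds 6-phosphofructokinase genes, the nitrogen list folylpolyglutamate synthase, the lectin list an A-agglutinin anchorage subunit, and the organelle list nuclear psbP-domain proteins. Lists with at least 3 tested members were compared with the other genes by camera with a preset correlation of 0.01, and again with an estimated correlation and with fry. Members were counted past the threshold over all genes and with p-values adjusted over the list alone. Single doses were compared with 10000 random lists matched in 20 expression bins, by the central 95%.

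Genes named in the text follow a rule fixed before the data were examined. For each contrast these were the 5 largest rises and 5 largest falls past the adjusted threshold with an absolute log2 fold change of at least 1, a mean log2 CPM of at least 1, a description and, in the first experiment, every treated library beyond every control library. The 2 members with the lowest p of each list, every beta-glucosidase past the threshold in any contrast and the 3 beta-glucosidases with the highest mean level were added. Genes followed across the second experiment, and any other gene so described, were chosen after their values were seen.

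Alternatives fixed beforehand were DESeq2 size factors, library size only, no low-count filter, the DESeq2 Wald test, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), a fold-change threshold of 1 on the log2 scale, the replicate number as a block, and leaving out each library. Counts thinned to equal depth, the cell division level as a covariate, leaving out each library for gene lists, and the contrasts of 6-BA added to NAA and NAA added to 6-BA were chosen after the data were seen. Where a library was left out, the lone library of its group was assumed to vary like the other groups. Contrasts that share control libraries were set beside 20 simulated repeats without change against the same controls.

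The pipeline was tested on simulated counts with 200 changed genes. For 6-BA against water it called 83% of genes changed by 1 and 99% of genes changed by 2 on the log2 scale, with 10 false calls of 192. For the interaction it called 62% and 97%, with 20 false calls of 179. That is a larger share of false calls than the adjusted threshold is set to allow. In the second experiment it called 50% of genes changed by 2 and 89.9% of those changed by 4 for 6-BA at any dose, and 56% and 83% for week. With no change simulated 0 of 26 lists passed by camera, and beta-glucosidase raised by 0.5 on the log2 scale gave adjusted p = 1.11e-23. Genes were simulated independently of one another, so this run cannot check list calls where genes vary together. Alignment to a genome and isoform-level values were not analysed here.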

Results

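Gene expression was measured by RNA sequencing in aerial tissue (young leaves, stems and shoots) of Dendrobium catenatum, an orchid whose polysaccharide-rich stems are used in traditional medicine. The plantlets were grown on culture medium with or without plant hormones. NAA (naphthaleneacetic acid) is a synthetic auxin and 6-BA (benzyladenine) a synthetic cytokinin. The series asked how these hormones change genes related to medicinal components. The study's title singles out beta-glucosidase, an enzyme class that releases glucose from glucosides and short glucans.

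In the first experiment, plantlets 2 months old were kept for 3 weeks on medium with distilled water, with NAA at 0.1 mg/L, with 6-BA at 1.0 mg/L, or with both hormones, with 2 libraries in each of the 4 groups. Total counts per library, in units of 1e6, were 39.4 and 40.1 with water, 37.2 and 34.3 with NAA, 54.3 and 52.9 with 6-BA, and 74.5 and 57.8 with both. In the second experiment, plantlets 9 months old received 6-BA at 0.5, at 1.0 or at 2.0 mg/L or none and were sampled after 2 or 4 weeks. There was 1 library for each of the 8 combinations, with totals of 15.1 to 16.3 in the same units. The labels call the 2 libraries of a treatment biological replicates without saying whether they came from separate culture vessels or harvests. P-values therefore measure only the spread between these samples. Replicate libraries differed by more than counting noise, with a chi-square per degree of freedom of 17.6 (water), 20.9 (NAA), 17.0 (6-BA) and 29.0 (both). No condition of the second experiment was replicated, and its tests took their spread from an additive model of time and dose.

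The comparison of 6-BA with water asks which transcripts respond to the cytokinin alone. Cytokinin dehydrogenase 6 (LOC110105324), an enzyme that degrades cytokinins, rose by 5.33 on the log2 scale (SE 0.26, adjusted p = 1.69e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2 libraries per group). Its level went from 0.664 and 0.374 CPM (counts scaled to a TMM-scaled library size of 1e6) in the water libraries to 22.6 and 19.4 CPM with 6-BA. The 2-oxoglutarate-dependent dioxygenase AOP1.2 (LOC110110694), of an enzyme family that modifies secondary metabolites, fell by 6.92 (SE 0.50, adjusted p = 0.000123), from 95.2 and 163 CPM to 0.400 and 1.74 CPM. A mannan endo-1,4-beta-mannosidase (LOC110100371), which cuts mannan chains such as the storage glucomannan of Dendrobium, fell by 4.22 (SE 0.41, adjusted p = 0.000458). A glucomannan 4-beta-mannosyltransferase (LOC110108629), which builds such chains, rose by 2.05 (SE 0.25, adjusted p = 0.00137).

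The other large rises with 6-BA were the 7-ethoxycoumarin O-deethylase LOC110095638, a cytochrome P450 (3.21, SE 0.25), pyruvate decarboxylase 1 (LOC110109144), an enzyme of alcoholic fermentation (4.34, SE 1.04), PLANT CADMIUM RESISTANCE 8 (LOC110091915, 3.45, SE 0.76) and a tricetin O-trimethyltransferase (LOC110101663, 3.10, SE 0.61). Pyruvate decarboxylase 1 differed between the 6-BA libraries, at 6.83 and 55.7 CPM, and its call was lost without 6-BA replicate 2 (2.14), either water library (6.28 and 3.54) or either library of the combined treatment (4.33 in each). The call of LOC110091915 was lost without 6-BA replicate 2 (2.46) or either water library (3.39 and 3.52), and that of LOC110101663 without 6-BA replicate 2 (1.67) or water replicate 1 (2.61). Large falls were seen in cytochrome P450 84A1-like (LOC110109066, -6.30, SE 0.86), cytochrome P450 93A2-like (LOC110106461, -6.04, SE 0.74), the AOP1 dioxygenase LOC110110825 (-5.67, SE 0.52) and a norcoclaurine 6-O-methyltransferase-like gene of the alkaloid-related list (LOC110098946, -4.52, SE 0.20, adjusted p = 1.2e-05). The AOP1 genes LOC110110821 and LOC110110825 lie on the same scaffold, at 6335511 to 6336692 and 6330661 to 6331859, and how reads shared by such copies were counted is not given in the sources used here.

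Of 27 beta-glucosidase genes tested with 6-BA alone, 2 rose, 6 fell and 19 did not pass over all genes, and the counts adjusted over the list alone were also 2 and 6. Beta-glucosidase 6-like (LOC110098121; scaffold NW_021319304.1, 278089 to 287638) fell by 4.67 (SE 0.35, adjusted p = 0.000137), from 5.16 and 6.21 CPM to 0.164 and 0.281 CPM. The furostanol glycoside 26-O-beta-glucosidase-like gene (LOC110100117; NW_021319992.1, 136710 to 143824), whose family activates defensive saponins, fell by 1.49 (SE 0.16, adjusted p = 0.000642). Beta-glucosidase 1-like (LOC110092217; NW_021319750.1, 216718 to 221380), the member with the highest mean level, fell by 0.78 on the log2 scale (SE 0.11, adjusted p = 0.00313), from 331 and 401 CPM to 221 and 207 CPM. Beta-glucosidase 22 (LOC110109493, -1.02, SE 0.15), beta-glucosidase BoGH3B (LOC110107269, -0.82, SE 0.10) and beta-glucosidase 18 (LOC110095267, -0.66, SE 0.13) were the other members that fell. Beta-glucosidase 2-like (LOC110095182, 1.78, SE 0.32) and beta-glucosidase 6 (LOC110115944, 0.64, SE 0.15) rose. Calls lost when a library was left out were those of LOC110095267 (water replicate 2, -0.49; either 6-BA library, -0.71 and -0.61), LOC110095182 (either water library, 1.62 and 1.97; 6-BA replicate 2, 1.55) and LOC110115944 (water replicate 1, 0.46; either 6-BA library, 0.70 and 0.58). As a list, beta-glucosidase did not differ from the other genes (camera, Down, adjusted p = 0.338; adjusted p = 0.79 with an estimated correlation). LOC110095267 overlaps another beta-glucosidase 18 gene, LOC110095269, on the same strand, so their values are uncertain.

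**Figure D1:**
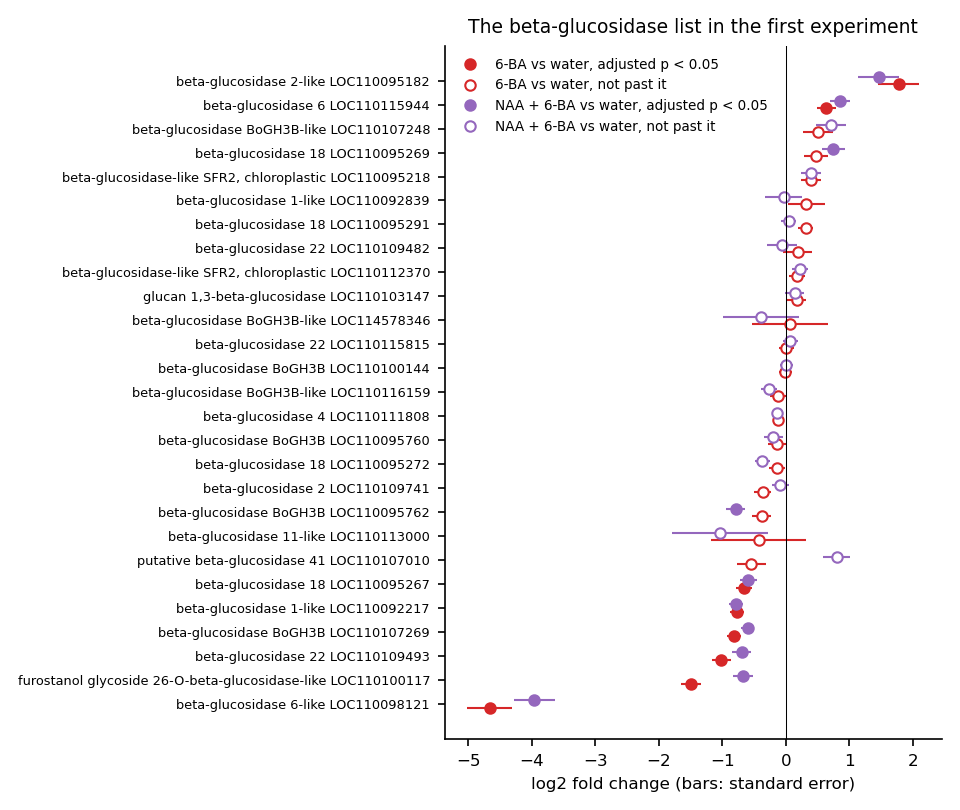
Log2 fold change of each of the 27 tested beta-glucosidase genes in the first experiment, with 6-BA (red) and with NAA plus 6-BA (purple) against water. Points are fitted values from 2 libraries per group, bars are standard errors, filled points are past adjusted p of 0.05, and beta-glucosidase 6-like (LOC110098121) lies at -4.67 and -3.96.

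Among polysaccharide genes, the mannan and glucomannan synthesis list had 1 of 25 members higher with 6-BA (LOC110108629) and none lower, with the same count adjusted over the list alone (camera adjusted p = 0.0914). In the cell wall loosening and hydrolysis list 12 members rose and 9 fell of 154 (16 and 9 adjusted over the list alone, camera adjusted p = 0.252). It holds the mannosidase LOC110100371 and xyloglucan endotransglucosylase/hydrolase 22 (LOC110098232), a wall-remodelling enzyme that rose by 2.48 (SE 0.18, adjusted p = 0.000123). Of 68 sucrose and starch genes, 4 rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.563). Sucrose synthase 2 (LOC110110417), which splits sucrose into building blocks for polysaccharides, rose by 0.98 (SE 0.22), a call lost without 6-BA replicate 2 (0.51) or either water library (0.91 and 1.06). An alpha-glucan phosphorylase (LOC110111898), which shortens starch chains, fell by 0.60 (SE 0.11), a call lost without water replicate 2 (-0.45) or either 6-BA library (-0.60 in each). The cellulose synthase list had 3 of 32 members higher and none lower, alike adjusted over the list alone (camera adjusted p = 0.146). In the sugar transport list 1 member rose and 2 fell of 37 (2 and 2 adjusted over the list alone, camera adjusted p = 0.454), among them the sucrose exporter SWEET14-like (LOC110098835, -1.16, SE 0.11).

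In the cytokinin response and turnover list, 11 of 50 genes rose and 3 fell with 6-BA (11 and 4 adjusted over the list alone), and the list as a whole was not past the threshold (camera adjusted p = 0.214). Besides cytokinin dehydrogenase 6, cytokinin dehydrogenase 4-like (LOC110102256) rose by 1.81 (SE 0.17, adjusted p = 0.00044), although it overlaps the gene LOC114580539. The auxin response list was higher (11 rose, 3 fell, 89 did not pass; 25 and 11 adjusted over the list alone, camera adjusted p = 0.00229). That call was lost with an estimated correlation (adjusted p = 0.326 with an estimated correlation). Its members include GH3.8 (LOC110103533, 2.31, SE 0.24), which inactivates auxin by joining it to amino acids, and PIN-LIKES 7 (LOC110093891, 1.12, SE 0.11), an intracellular auxin carrier. In the other hormone response list 9 members rose and 6 fell of 84 (21 and 10 adjusted over the list alone, camera adjusted p = 0.074).

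Mannose-binding lectins, which store protein and bind insect and fungal sugars, were lower with 6-BA as a list (0 rose, 6 fell, 20 did not pass; 2 and 8 adjusted over the list alone, camera adjusted p = 0.00838 and adjusted p = 0.326 with an estimated correlation). Mannose-specific lectin-like LOC110114174 fell by 6.14 (SE 0.66) and mannose-specific lectin LOC110101453 by 1.69 (SE 0.24). Lectin genes are a family of close copies between which reads are easily shared, and single members are uncertain. Cytosolic ribosomal protein genes were lower by a median of -0.20, with 2 of 211 past the threshold (0 adjusted over the list alone, camera adjusted p = 2.04e-10 and adjusted p = 0.79 with an estimated correlation). In the heat shock and chaperone list 0 members rose and 8 fell of 57 (0 and 10 adjusted over the list alone, camera adjusted p = 0.146). The 17.4 kDa class III heat shock protein (LOC110097211, -1.38, SE 0.11) and heat shock cognate 70 kDa protein 2 (LOC110108419, -1.22, SE 0.11), chaperones of protein folding, were among them. Light harvesting and pigment lists did not pass (photosynthesis 2 higher and 1 lower of 55, camera adjusted p = 0.0802; chlorophyll synthesis 1 and 0 of 11, 0.229), and no organelle transcript of 10 passed (0.397). Cell division (1 and 2 of 65, camera adjusted p = 0.454), histone (0 and 1 of 51, 0.966), and shoot meristem and leaf patterning genes (4 and 1 of 57, 0.0802) did not pass as lists. The same held for phenylpropanoid and lignin (5 and 6 of 71, 0.966), flavonoid synthesis (8 and 5 of 55, 0.252), terpenoid and sterol backbone (0 and 3 of 42, 0.934) and alkaloid-related genes (3 and 2 of 44, 0.966). Defence and chitinase genes had 11 higher and 13 lower of 141 (0.562), and nitrate and nitrogen genes 3 and 4 of 68 (0.966). Root markers, for a tissue that the labels do not list, had 1 member higher and 2 lower of 18 (camera adjusted p = 0.966), and floral markers had 1 higher and 2 lower of 47 (camera adjusted p = 0.966).

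In total 1420 of 19420 genes passed the threshold with 6-BA, of which 604 rose and 816 fell. Of these, 147 rose and 344 fell by at least 1 on the log2 scale. The count was 799 without 6-BA replicate 1, 494 without 6-BA replicate 2, 707 without water replicate 1 and 603 without water replicate 2.

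**Figure D2:**
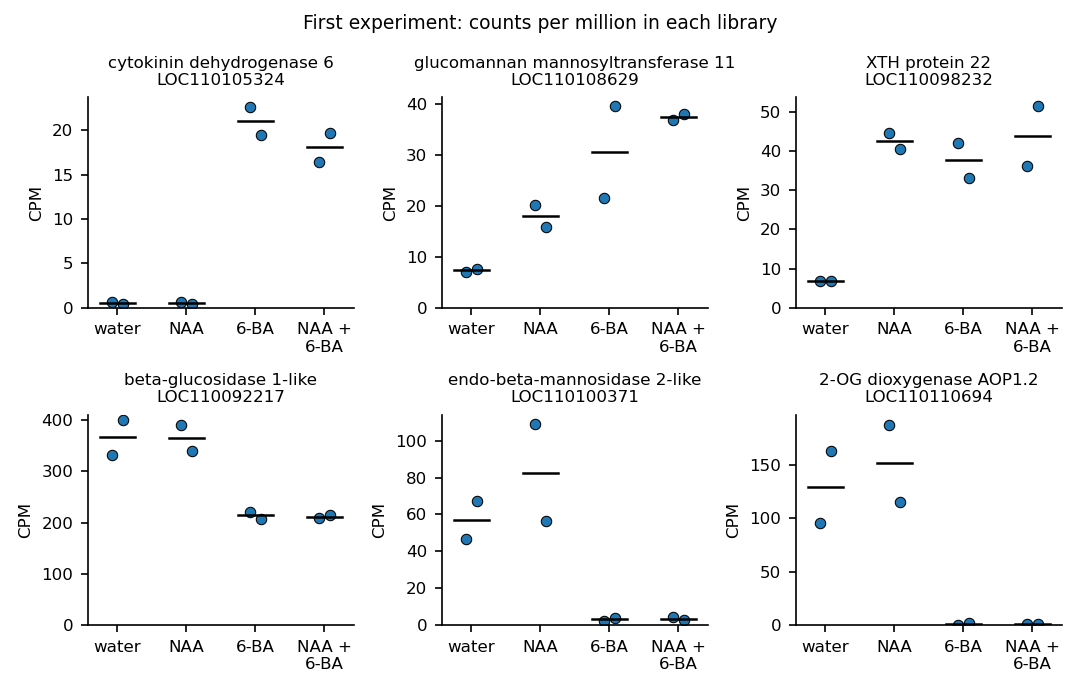
Level (CPM) of 6 genes in each of the 8 libraries of the first experiment. Each point is a library and each line the mean of the 2 libraries of a group, and cytokinin dehydrogenase 6 (LOC110105324) lies at 16.4 to 22.6 CPM in the 4 libraries with 6-BA against 0.374 to 0.664 CPM in the 4 without.

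Effects of 6-BA were next taken over plants with and without NAA, 4 libraries against 4. Cytokinin dehydrogenase 6 (LOC110105324) rose by 5.24 (SE 0.19, adjusted p = 6.72e-07), the glucomannan mannosyltransferase LOC110108629 by 1.54 (SE 0.23, adjusted p = 0.00266), and the mannosidase LOC110100371 fell by 4.41 on the log2 scale (SE 0.29, adjusted p = 2.78e-05). RADIALIS-like 3 (LOC110104912), a MYB-type regulator, rose by 3.23 (SE 0.46), and early nodulin-93-like (LOC110114034) by 2.60 (SE 0.40). Polygalacturonase QRT3-like (LOC110098421), a pectin-degrading enzyme, fell by 4.69 (SE 0.40, adjusted p = 9.13e-05), and the lectin LOC110114174 was lower (-5.6, SE 0.45). Of 27 beta-glucosidases 3 rose and 7 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.499), led by LOC110098121 (-3.91, SE 0.32) and LOC110107269 (-0.77, SE 0.07). LOC110092217 fell by 0.78 on the log2 scale (SE 0.08) and LOC110100117 by 1.01 (SE 0.19).

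With the larger groups, 17 of 50 cytokinin genes rose and 7 fell (17 and 8 adjusted over the list alone, camera adjusted p = 0.0125 and adjusted p = 0.564 with an estimated correlation). Without NAA replicate 1 that list had adjusted p = 0.0542. Of the auxin response genes 28 rose, 6 fell and 68 did not pass (40 and 10 adjusted over the list alone, camera adjusted p = 0.000249 and adjusted p = 0.16 with an estimated correlation), including auxin response factor 2A-like (LOC110100115, 0.68, SE 0.06). The lectin list was lower (2 rose, 10 fell, 14 did not pass; 3 and 10 adjusted over the list alone, camera adjusted p = 0.00585 and adjusted p = 0.266 with an estimated correlation). Of 56 heat shock genes 1 rose and 16 fell (1 and 21 adjusted over the list alone, camera adjusted p = 0.00404 and adjusted p = 0.702 with an estimated correlation). Of 211 ribosomal protein genes 0 rose and 34 fell (0 and 34 adjusted over the list alone, camera adjusted p = 2.38e-13 and adjusted p = 0.702 with an estimated correlation). Shoot meristem and leaf patterning genes were higher as a list (6 rose, 3 fell of 57, alike adjusted over the list alone, camera adjusted p = 0.00572 and adjusted p = 0.702 with an estimated correlation). They include TCP20-like (LOC110111827, 0.80, SE 0.16), a growth regulator that rose, and WUSCHEL-related homeobox 4 (LOC110092438, -0.98, SE 0.21), a stem-cell regulator of the vascular cambium that fell. Root markers showed SHORT-ROOT-like (LOC110095590, -1.94, SE 0.18) and casparian strip membrane protein 2-like (LOC110102706, -1.75, SE 0.28) lower, within a list that had 1 member higher and 2 lower of 18 (1 and 2 adjusted over the list alone, camera adjusted p = 0.977).

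Over NAA, 2582 of 19303 genes passed, 1142 higher and 1440 lower. That split depended on the scaling, with 1443 higher and 1161 lower by library size only, and 1315 higher and 1126 lower by limma on log2(FPKM + 1). The count was 1605 without 6-BA replicate 1, 1526 without 6-BA replicate 2, 1568 without replicate 1 of the combined treatment and 1542 without water replicate 2.

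A contrast of 6-BA added to NAA against NAA alone, chosen after the data were seen, shares no library with 6-BA against water. In it cytokinin dehydrogenase 6 (LOC110105324) rose by 5.13 (SE 0.27, adjusted p = 2.96e-05), the dioxygenase LOC110110694 fell by 7.05 (SE 0.49, adjusted p = 0.00011) and the mannosidase LOC110100371 by 4.58 (SE 0.40). The beta-glucosidases LOC110098121 (-3.26, SE 0.32), LOC110092217 (-0.79, SE 0.11) and LOC110107269 (-0.73, SE 0.10) fell. Across genes the log2 fold changes of the 2 contrasts had a Pearson correlation of 0.631, where genes are not independent replicates. Both contrasts called 179 genes higher and 380 lower, against 11.7 and 29.7 for independent lists of those sizes, and 88.9% of the 1420 genes had the same sign. It passed 1083 genes, 376 higher and 707 lower (527 and 624 by library size only), with 581 genes without NAA replicate 1, 387 without replicate 1 of the combined treatment and 617 without its replicate 2.

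**Figure D3:**
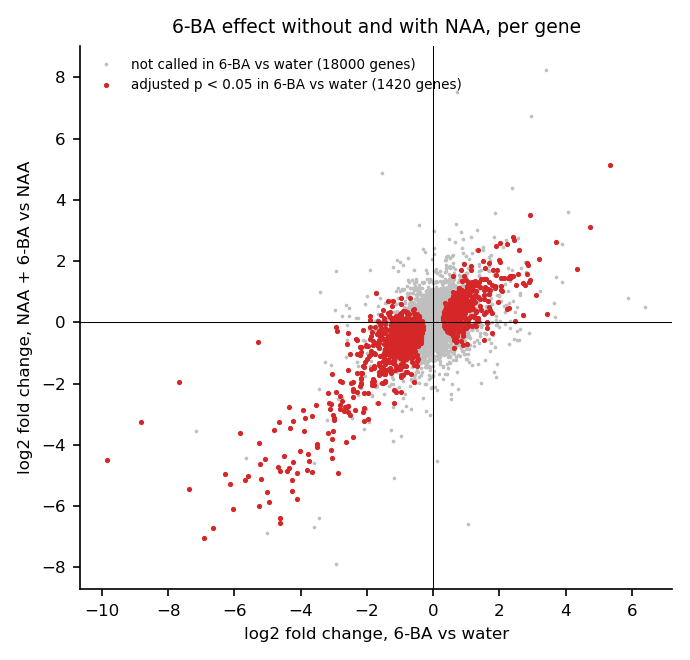
Log2 fold change of each of the 19420 tested genes with 6-BA against water (horizontal) and with NAA plus 6-BA against NAA (vertical). Red points are the 1420 genes past adjusted p of 0.05 in the horizontal comparison, of which 88.9% keep their sign in the vertical one.

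The comparison of NAA with water asks which transcripts respond to the auxin alone. Wall enzymes were among the largest rises. Xyloglucan endotransglucosylase/hydrolase 22 (LOC110098232) rose by 2.66 on the log2 scale (SE 0.18, adjusted p = 0.000463, edgeR's quasi-likelihood test), from 6.72 and 6.81 CPM to 44.7 and 40.6 CPM, and xyloglucan endotransglucosylase/hydrolase 30 (LOC110115141) rose by 2.10 (SE 0.18, adjusted p = 0.000852). Gibberellin 2-beta-dioxygenase 8-like (LOC110108465), which inactivates gibberellins, rose by 2.29 (SE 0.27, adjusted p = 0.00306). Nudix hydrolase 13 (LOC110111845, 2.25, SE 0.14) and the ethylene-responsive factor ERF039-like (LOC110114282, 2.07, SE 0.25) completed the largest rises. The largest falls were U-box protein 19-like (LOC110108815, -2.38, SE 0.21), a ubiquitin ligase, mannose-specific lectin-like LOC110108726 (-2.16, SE 0.39), zinc finger CCCH protein 2 (LOC110107925, -1.75, SE 0.16) and the ubiquitin ligases ATL4-like (LOC110114333, -1.62, SE 0.30) and XERICO (LOC110107177, -1.57, SE 0.11). XERICO regulates the level of abscisic acid. The call of LOC110114333 was lost without each of the 4 water and NAA libraries (-1.84 to -1.42), and that of LOC110108726 without water replicate 1 (-1.81) or NAA replicate 2 (-1.75).

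Of 27 beta-glucosidases 1 rose with NAA, beta-glucosidase 2-like (LOC110095182, 1.82, SE 0.33, from 0.613 and 0.774 CPM to 2.93 and 1.97 CPM), and none fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.887). The call was lost without NAA replicate 1 (1.5) or either water library (1.66 and 2.00). The mannan and glucomannan synthesis list was higher with NAA (2 rose, 0 fell, 23 did not pass; 3 and 0 adjusted over the list alone, camera adjusted p = 0.000499 and adjusted p = 0.359 with an estimated correlation). Its called members were the glucomannan mannosyltransferases LOC110102411 (0.67, SE 0.11) and LOC110108629 (1.28, SE 0.25), whose calls were lost without either water library (0.61 and 0.74 for the former, 1.23 and 1.34 for the latter), and for LOC110108629 also without NAA replicate 1 (1.10) or either library of the combined treatment (1.28). Of 32 cellulose synthase genes 2 rose (3 adjusted over the list alone), cellulose synthase-like D2 (LOC110097221, 0.98, SE 0.11) and cellulose synthase A5 (LOC110114259, 0.79, SE 0.11; lost without water replicate 1, 0.69), and none fell (camera adjusted p = 0.264). In the cell wall loosening and hydrolysis list 11 members rose and 8 fell of 154 (16 and 9 adjusted over the list alone, camera adjusted p = 0.769).

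The cytokinin response and turnover list was lower with NAA (0 rose, 2 fell, 48 did not pass, alike adjusted over the list alone, camera adjusted p = 0.0135 and adjusted p = 0.359 with an estimated correlation). The call was lost without water replicate 2 (adjusted p = 0.0908) or NAA replicate 1 (adjusted p = 0.0973). Its called members were response regulator ORR9 (LOC110097157, -0.88, SE 0.14), a negative regulator of cytokinin signalling, and cytokinin dehydrogenase 5 (LOC110095507, -1.15, SE 0.21). Without water replicate 2 or NAA replicate 1 the calls of LOC110097157 (-0.78 and -0.81) and LOC110095507 (-1.07 and -1.03) were lost, the latter also without water replicate 1 (-1.22). The other hormone response list was higher (9 rose, 1 fell of 84; 18 and 4 adjusted over the list alone, camera adjusted p = 0.0393 and adjusted p = 0.927 with an estimated correlation), a call lost without water replicate 2 (adjusted p = 0.137) or NAA replicate 2 (adjusted p = 0.439). TIFY 10a-like (LOC110113635), a repressor of jasmonate responses, rose by 1.14 (SE 0.15), a call lost without water replicate 1 (1.11). The auxin response list had 1 member higher, SAUR78 (LOC110097212, 0.95, SE 0.16; lost without either water library, 1.04 and 0.87, or NAA replicate 1, 0.90), and 1 lower of 103, alike adjusted over the list alone (camera adjusted p = 0.818). Photosynthesis genes were higher by a median of 0.10 (0 rose, 1 fell of 55, camera adjusted p = 0.00598 and adjusted p = 0.927 with an estimated correlation), and the 1 that fell was plastocyanin-like LOC110108071 (-1.2, SE 0.21; lost without water replicate 1, -0.82, or NAA replicate 1, -1.00). The call of the list was lost without water replicate 2 (adjusted p = 0.712) or NAA replicate 2 (adjusted p = 0.876).

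NAA alone passed 434 genes, 274 higher and 160 lower, and the count was 112 without water replicate 1, 182 without water replicate 2 and 208 without NAA replicate 1. Averaged over 6-BA, 0 of 19303 genes passed for NAA by edgeR's quasi-likelihood test, with 1908 at an unadjusted p under 0.05 and 214 by DESeq2. Lists past the threshold by camera in this contrast included mannan and glucomannan synthesis, cytokinin response and turnover, photosynthesis, histone and ribosomal protein. Each of these calls was lost with an estimated correlation, and each was lost without some library. For NAA added to 6-BA, a contrast chosen after the data were seen, 0 genes passed by edgeR (11 without 6-BA replicate 1, 1 without either library of the combined treatment), with 1073 at an unadjusted p under 0.05 and 40 by DESeq2. Of the 434 genes called with NAA alone, 268 had the same sign when NAA was added to 6-BA, and their median change in the called direction was 0.05, against a median size of 0.79 with NAA alone. Because NAA and 6-BA shared the water libraries, their overlap was set beside unchanged groups simulated against the same controls. NAA and 6-BA called 82 genes higher in both, against 8.5 for independent lists, and 363 of the 434 NAA genes had the same sign with 6-BA. The correlation of their log2 fold changes across genes was 0.264 against a simulated 0.508, and the covariance 0.0535 against 0.0301. The observed changes were edgeR's fitted values, and the simulated ones differences of log2 CPM with a prior count of 2. These are unlike measures. The share with the same sign was 83.6% of the 434 genes, and 66.9% of all genes in the simulation. As the 434 were chosen for their difference from the same water libraries, these shares cannot be compared. The 2 water libraries were not split between the contrasts, and part of these values comes from the shared controls.

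With NAA and 6-BA together against water, cytokinin dehydrogenase 6 (LOC110105324) rose by 5.11 (SE 0.26, adjusted p = 1.95e-05, edgeR's quasi-likelihood test), RADIALIS-like 3 (LOC110104912) by 3.84 (SE 0.66) and the P450 LOC110095638 by 3.24 (SE 0.25). Xyloglucan endotransglucosylase/hydrolase 22 (LOC110098232) rose by 2.7 (SE 0.18, adjusted p = 9.04e-05) and the poly(ADP-ribose) polymerase-like gene SRO2 (LOC110093112) by 2.50 (SE 0.53). The dioxygenase LOC110110694 fell by 6.82 (SE 0.49, adjusted p = 0.00011), and cytochrome P450 93A2-like (LOC110106461, -6.04, SE 0.72), nuclear factor Y subunit C-9-like (LOC110113050, -5.55, SE 0.44), AOP1 (LOC110110821, -5.19, SE 0.44) and the receptor kinase ZmPK1 (LOC110094981, -5.07, SE 0.69) were also lower. The call of RADIALIS-like 3 was lost without either water library (4.04 and 3.67), and that of SRO2 without either library of the combined treatment (2.67 and 2.33).

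Of 27 beta-glucosidases 3 rose and 7 fell with both hormones (5 and 8 adjusted over the list alone, camera adjusted p = 0.353). LOC110098121 fell by 3.96 (SE 0.32, adjusted p = 0.000183), LOC110092217 fell by 0.79 on the log2 scale (SE 0.11, adjusted p = 0.00279), and BoGH3B (LOC110095762), which overlaps LOC110095761, fell by 0.79 on the log2 scale (SE 0.15), a call lost without water replicate 2 (-0.72) or replicate 2 of the combined treatment (-0.70). Beta-glucosidase 6 (LOC110115944) rose by 0.85 (SE 0.15), a call lost without water replicate 1 (0.67) or replicate 1 of the combined treatment (0.69). The mannan and glucomannan synthesis list was higher (3 rose, 0 fell of 25, alike adjusted over the list alone, camera adjusted p = 0.0479 and adjusted p = 0.672 with an estimated correlation). Called members included LOC110108629 (2.34, SE 0.25) and its neighbour LOC110108619 (0.68, SE 0.15), a copy with the same annotation. The list was not past the threshold without water replicate 1 (adjusted p = 0.457) or replicate 2 of the combined treatment (adjusted p = 0.146), and the call of LOC110108619 was lost without either water library (0.56 and 0.81) or replicate 1 of the combined treatment (0.56). The mannosidase LOC110100371 fell by 4.03 (SE 0.40).

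The auxin response list was higher with both hormones (18 rose, 2 fell of 103; 23 and 4 adjusted over the list alone, camera adjusted p = 0.00174 and adjusted p = 0.308 with an estimated correlation), with auxin response factor 2A-like (LOC110100115) up by 0.82 (SE 0.09). Lectins were lower (0 rose, 4 fell of 26; 0 and 6 adjusted over the list alone, camera adjusted p = 0.00306 and adjusted p = 0.308 with an estimated correlation). Heat shock genes were lower (0 rose, 13 fell of 57; 0 and 16 adjusted over the list alone, camera adjusted p = 0.00639 and adjusted p = 0.673 with an estimated correlation). LOC110108419 (-1.52, SE 0.11) and LOC110097211 (-1.48, SE 0.11) were among them. Past the threshold by camera were also ribosomal protein (Down, adjusted p = 0.000873), photosynthesis (Up, adjusted p = 0.00567), shoot meristem and leaf patterning (Up, adjusted p = 0.0137) and flavonoid synthesis (Up, adjusted p = 0.0327), with adjusted p of 0.672 to 0.763 with an estimated correlation. Each of those 4 was lost without some library: ribosomal protein without water replicate 1 (0.523) or replicate 1 of the combined treatment (0.79), and the others without its replicate 2 (photosynthesis 0.106, shoot meristem 0.189, flavonoid 0.146). Photosynthesis (0.56) and shoot meristem (0.132) were also lost without water replicate 2, and flavonoid synthesis without either NAA library (0.0503 in each).

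Both hormones together passed 1374 genes, 585 higher and 789 lower, with 637 and 644 genes without replicates 1 and 2 of the combined treatment and 729 and 569 without water replicates 1 and 2. Genes called in the same direction with 6-BA alone numbered 386 higher and 588 lower, against 18.2 and 33.2 for independent lists. The covariance of the log2 fold changes was 0.2339 against 0.0302 for simulated unchanged groups that share the controls, and the correlation 0.833 against 0.529. For NAA alone and both hormones the shared calls were 108 higher and 106 lower, against 8.3 and 6.5, with a covariance of 0.0645 against 0.0301 and a correlation of 0.334 against 0.508. The simulated values of this last pair were taken from the simulation of NAA and 6-BA. As above, simulated changes were differences of log2 CPM and observed ones fitted values, which are unlike measures. Each of these pairs of contrasts shares the water libraries, which can raise the shared calls above those of independent lists. That excess alone therefore does not show a shared response.

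The interaction term asks whether the 6-BA effect differs with NAA. The wall enzymes LOC110098232 (-2.44, SE 0.24, adjusted p = 0.016, edgeR's quasi-likelihood test) and LOC110115141 (-2.17, SE 0.25, adjusted p = 0.016) had negative terms. LOC110098232 was raised to a similar level by each hormone and by both, while LOC110115141 was at 18.3 and 16.7 CPM with NAA against 3.50 to 5.21 CPM in the other 6 libraries. Chaperone dnaJ 20-like (LOC110092633, -2.12, SE 0.28), the stress-associated zinc finger protein 5 (LOC110101170, -1.84, SE 0.26), EXORDIUM-like 2 (LOC110114862, -1.65, SE 0.27), a brassinosteroid-responsive growth gene family, and cellulose synthase-like D2 (LOC110097221, -0.98, SE 0.15) also had negative terms. Positive terms were those of U-box protein 19-like (LOC110108815, 2.67, SE 0.28), zinc finger CCCH protein 2 (LOC110107925, 1.92, SE 0.22), phosphoenolpyruvate carboxylase kinase 1 (LOC110096942, 1.78, SE 0.28), bHLH086 (LOC110102628, 1.65, SE 0.28), bZIP 11-like (LOC110113543, 1.58, SE 0.27), pathogenesis-related protein 1-like (LOC110102547, 1.54, SE 0.22) and the sugar carrier SWEET2a-like (LOC110112344, 1.18, SE 0.19).

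No beta-glucosidase passed for the interaction over all genes (0 and 0 of 27; 2 and 1 adjusted over the list alone, camera adjusted p = 0.49). The lists lower by camera were mannan and glucomannan synthesis (0 and 0 of 25; 0 and 1 adjusted over the list alone; adjusted p = 0.00832; adjusted p = 0.685 with an estimated correlation), other hormone response (0 and 0 of 84; 4 and 13 adjusted over the list alone; adjusted p = 0.00832; adjusted p = 0.825 with an estimated correlation) and heat shock and chaperone (0 and 1 of 57, alike adjusted over the list alone; adjusted p = 0.0141; adjusted p = 0.831 with an estimated correlation). In total 101 genes passed, 30 positive and 71 negative, with 1581 at an unadjusted p under 0.05 and 383 past the threshold by DESeq2. The count fell to 0 without either water library, 7 without NAA replicate 1, 4 and 28 without 6-BA replicates 1 and 2, and 5 without replicate 1 of the combined treatment, and it was 204 without NAA replicate 2. In each of these fits all 101 genes kept their sign, with a median ratio to the full fit of 0.94 to 1.06. The genes were chosen in the full fit, and each smaller fit reuses its remaining libraries. Kept signs are therefore no separate support for the calls.

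In the second experiment, older plantlets received graded 6-BA. Cytokinin dehydrogenase 6 (LOC110105324) had 3 counts without 6-BA and 38, 25 and 15 counts at rising doses after 2 weeks, and 5 counts followed by 13, 171 and 63 after 4 weeks. Its 6-BA term over all doses was 3.67 (SE 1.12, adjusted p = 0.856 by edgeR's quasi-likelihood test). Beta-glucosidase 1-like (LOC110092217) was at 112, 168, 231 and 202 CPM after 2 weeks and at 200, 1870, 430 and 193 CPM after 4 weeks. The glucomannan mannosyltransferase LOC110108629 was at 2.36, 135, 0.453 and 2.31 CPM after 2 weeks and 219, 2.71, 0 and 144 CPM after 4 weeks, where its count of 0 at 1.0 mg/L is under the limit of detection. The mannosidase LOC110100371 had 274, 121, 17 and 17 counts after 2 weeks and 6, 7, 34 and 19 after 4 weeks. Beta-glucosidase 22 (LOC110109482) was at 823, 536, 660 and 851 CPM after 2 weeks and at 145, 1050, 703 and 339 CPM after 4 weeks. Beta-glucosidase 6-like (LOC110098121) had 9, 12, 3 and 1 counts after 2 weeks and 3, 9, 11 and 6 after 4 weeks. The furostanol glycoside 26-O-beta-glucosidase-like gene (LOC110100117) had 81, 358, 0 and 1 counts, then 894, 4, 4 and 2045. Cytokinin dehydrogenase 4-like (LOC110102256) had 161, 221, 145 and 124 counts, then 143, 126, 454 and 226. These genes were picked after their values were seen, and not all genes followed are printed here. Differences between single libraries have no replicate check.

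**Figure D4:**
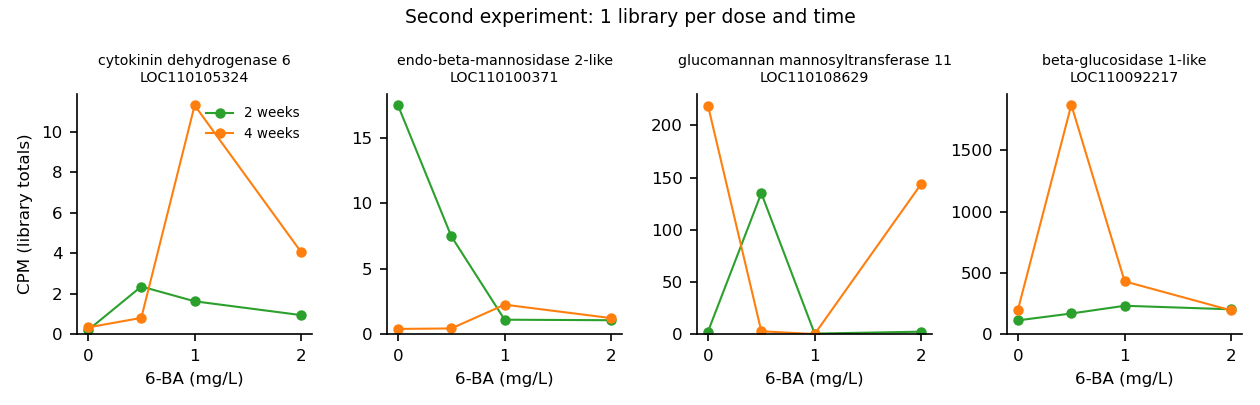
Level (CPM) of 4 genes against 6-BA dose (mg/L) in the second experiment, after 2 weeks (green) and 4 weeks (orange). Each point is 1 library, so the plot has no error bars, and beta-glucosidase 1-like (LOC110092217) lies at 1870 CPM at 0.5 mg/L after 4 weeks and at 112 to 430 CPM in the other 7 libraries.

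By edgeR's quasi-likelihood test 0 of 21267 genes passed for 6-BA at any dose against none, with 498 at an unadjusted p under 0.05 and 6 past the threshold by DESeq2. For the slope on dose 0 genes passed, with 430 at an unadjusted p under 0.05 and 5 by DESeq2. These 498 and 430 genes were 2.34% and 2.02% of those tested, fewer than a cutoff of 0.05 gives when nothing changes. By camera with a preset correlation the ribosomal protein (Down, adjusted p = 4.49e-18), histone (Down, adjusted p = 3.11e-08), cell division (Down, adjusted p = 0.000392) and photosynthesis (Up, adjusted p = 0.000254) lists were past the threshold at any dose. The adjusted p was 0.712 for each of them with an estimated correlation, and none of their members passed. Without the 4-week library at 0 mg/L cell division had adjusted p = 0.0777, and without the 2-week library at 0 mg/L photosynthesis had adjusted p = 0.102. Auxin response (Down, 0.00142), organelle transcripts (Up, 0.00135), cell wall loosening (Down, 0.00328) and alkaloid-related genes (Up, 0.0107) were past it too, each with adjusted p = 0.712 with an estimated correlation, and each was lost without the 4-week library at 0 mg/L (0.0777, 0.565, 0.219 and 0.318). Sucrose and starch (Up, 0.0313) and terpenoid genes (Up, 0.0272) were lost without that library (0.262 and 0.0777) and without others, and had adjusted p = 0.712 with an estimated correlation. For the slope on dose, ribosomal protein (Down, adjusted p = 1.18e-23), histone (Down, adjusted p = 6.92e-07) and organelle transcripts (Up, adjusted p = 2.01e-05) led the lists, with adjusted p = 0.609 with an estimated correlation. The histone and organelle calls were lost without the 2-week library at 2.0 mg/L (0.227 and 0.101). The beta-glucosidase list was not past the threshold at any dose (median 0.17, camera adjusted p = 0.617) or for the slope (median 0.04 and mean -0.07, camera Down, adjusted p = 0.9).

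The cell division list, whose genes drive DNA replication and mitosis, varied between libraries. Its mean level relative to the 8 libraries was 0.50, 0.87, -0.91 and -1.00 in order of dose after 2 weeks and 1.2, -1.06, -0.89 and 1.29 after 4 weeks, on the log2 CPM scale. Histone genes, which package newly replicated DNA, were at 0.52, 0.95, -0.56 and -1.17 and at 1.23, -0.94, -0.81 and 0.78. Shoot meristem and leaf patterning, mannan and glucomannan synthesis, cell wall loosening and auxin response lay on the same side of their means as cell division in 8 of 8 libraries, beta-glucosidase in 7 and photosynthesis in 3. These levels fall into 2 separate clusters of libraries, so no correlation across libraries was computed. The first principal component held 57.6% of the variance and placed the 4 libraries with positive cell division means at 33.3 to 115.5 and the other 4 at -99.9 to -65.6.

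**Figure D5:**
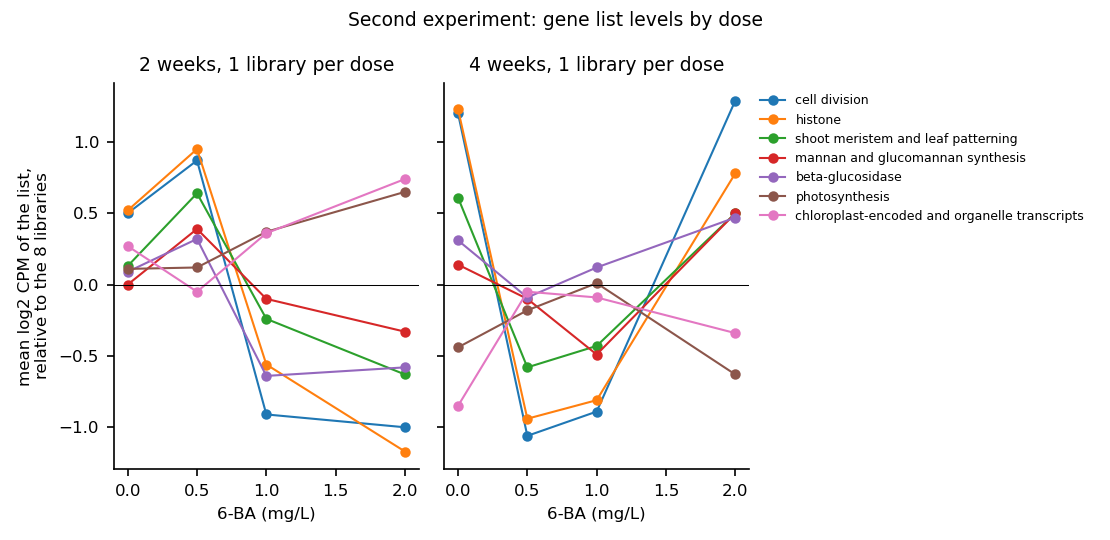
Mean log2 CPM of 7 gene lists relative to the 8 libraries of the second experiment, against 6-BA dose (mg/L), after 2 weeks (left) and 4 weeks (right). Each point is 1 library, and cell division and histone genes lie below 0 at 1.0 and 2.0 mg/L after 2 weeks but below 0 at 0.5 and 1.0 mg/L after 4 weeks.

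Each dose was also set against 0 mg/L of the same week as a ratio of 2 libraries, without a test. List medians were compared with the central 95% of 10000 random lists of the same size matched on expression. Outside it lay 13, 9 and 19 of the 26 lists in dose order after 2 weeks, and 14, 16 and 9 after 4 weeks. The random genes were drawn independently, whereas genes of a list can vary together. Any 2 unlike libraries can therefore put lists outside, and these counts and percentiles do not show a response to dose. The beta-glucosidase list had medians of 0.21, 0.12 and 0.01 after 2 weeks (percentiles 95.9, 88.5 and 63.2) and of 0.45, 0.09 and 0.25 after 4 weeks (percentiles 98.4, 71.8 and 98.3). Mannose-binding lectins had a median of 0.73 at 0.5 mg/L after 2 weeks and negative medians, from -0.87 to -0.30, in the other 5 comparisons. The share of all counts in lectin genes moved the other way, at 6.63%, 2.03%, 8.85% and 7.63% in order of dose after 2 weeks. After 4 weeks it was 1.23%, 7.2%, 4.92% and 3.25%. Mannose-specific lectin LOC110101453 was at 30000, 7300, 42800 and 33600 CPM after 2 weeks and at 2250, 33600, 21200 and 10800 CPM after 4 weeks. With library size only in place of TMM, the median of all genes shifted from near 0 to 0.10, -0.17 and -0.23 after 2 weeks and to -0.28, -0.21 and -0.02 after 4 weeks, and values are given relative to the TMM scale.

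Between 4 and 2 weeks the photosynthesis list was lower (median -0.62, 0 of 55 genes past over all genes, 0 rose and 7 fell adjusted over the list alone, camera adjusted p = 8.41e-25 and adjusted p = 0.298 with an estimated correlation). The chlorophyll a-b binding proteins LOC110099194 (-1.99, SE 0.26, adjusted p = 0.919 by edgeR's quasi-likelihood test) and LOC110113998 (-1.69, SE 0.26, adjusted p = 0.919), which harvest light, had the lowest p in it. Chlorophyll synthesis (median -0.46; 0 and 6 of 11 adjusted over the list alone, camera adjusted p = 2.2e-08 and adjusted p = 0.298 with an estimated correlation) and organelle transcripts (median -0.66; 0 and 2 of 26 adjusted over the list alone, camera adjusted p = 8.69e-12 and adjusted p = 0.298 with an estimated correlation) were lower as well, with rbcL (-1.09, SE 0.23) and psbC (-1.12, SE 0.23) as examples. Terpenoid backbone (camera adjusted p = 0.00025) and heat shock genes (camera adjusted p = 0.00152) were also lower, with adjusted p of 0.355 and 0.298 with an estimated correlation. These 5 calls held without each library in turn. By edgeR 0 genes passed between the weeks, with 998 (4.69%) at an unadjusted p under 0.05 and 82 past the threshold by DESeq2. That share of 4.69% is no more than the cutoff gives when nothing changes. With library size only the median of all genes shifted to 0.20 for week and to -0.11 for any dose.

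Genes called with 6-BA in the first experiment were finally followed in the second, which shares no library with it. Of the 604 that rose, 594 were tested, and 56.6% were higher with 6-BA at any dose. Of the 816 that fell, 729 were tested, and 41.3% were lower. Camera, a model-based and not an exact test, gave p = 0.238 for the former set and p = 0.271 for the latter, Up in both. A second measure, the mean difference in TMM-scaled log2 CPM from the untreated library of each week, needs no fit and was used for an exact test. By it 49.6% of all 1323 genes had the same sign, and 9 of the 16 ways to name the untreated library of each week gave a share as large or larger (exact one-sided p = 0.562, where 0.0625 is the smallest this design allows and the highest other share was 58.5%). For the 147 genes that rose by at least 1 on the log2 scale, 139 were tested and 66.9% were higher (camera, not an exact test, Up, p = 0.00856). For the 344 genes that fell by at least 1, 261 were tested and 38.3% were lower (camera, not an exact test, Up, p = 0.418). Without the 4-week library at 0 mg/L the direction for the 816 genes that fell was Down (camera, not an exact test), but the set was not past the threshold. The median of those tested was 0.02 and 47.3% were lower. Without the 2-week library at 0 mg/L the set was past the threshold in the Up direction (camera, not an exact test, p = 0.014).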

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

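The tests of library depth and of the water libraries were chosen only after the interaction result was seen. The following results were singled out because the effect of 6-BA differed between plants with and without NAA by a tested interaction term. It held for 101 genes past the threshold, and the count was 37 with the replicate number as a block. As given above, few or none of these calls remained without some single libraries. In simulated counts this contrast gave 20 false calls of 179, a larger share than the adjusted threshold is set to allow. The calls are therefore uncertain. Positive terms were those of U-box protein 19-like (LOC110108815, 2.67), zinc finger CCCH protein 2 (LOC110107925, 1.92), phosphoenolpyruvate carboxylase kinase 1 (LOC110096942, 1.78), bHLH086 (LOC110102628, 1.65) and bZIP 11-like (LOC110113543, 1.58). Negative terms were those of the xyloglucan endotransglucosylase/hydrolases 22 (LOC110098232, -2.44) and 30 (LOC110115141, -2.17), dnaJ 20-like (LOC110092633, -2.12), stress-associated protein 5 (LOC110101170, -1.84) and EXORDIUM-like 2 (LOC110114862, -1.65). Lower lists were mannan and glucomannan synthesis (adjusted p = 0.00832; adjusted p = 0.685 with an estimated correlation), other hormone response (adjusted p = 0.00832; adjusted p = 0.825 with an estimated correlation), and heat shock and chaperone (adjusted p = 0.0141; adjusted p = 0.831 with an estimated correlation).

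Of the 101 genes, NAA was the group furthest from the other 3 for 52 (51.5%) and water for 40 (39.6%), against 29.4% and 27.4% of all genes. Unequal depth was excluded as the main source, since 96% of the calls were kept after thinning to equal depth. The 52 genes with NAA apart were grouped so because the other 3 groups spread least when NAA was left out. Water did not lie close to 6-BA and the combined treatment in each of them. LOC110102140, for example, was at 1.23 with NAA, -0.97 with 6-BA and -1.05 with both, relative to water on the log2 scale. No explanation other than depth was tested for these 52 genes.

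For the 40 genes with water apart, handling or harvest of the water libraries remained open. In the second experiment the 25 genes higher in all treated groups than in water had a median of 0.30 with 6-BA (camera, not an exact test, Up, p = 0.361, and p = 0.565 with an estimated correlation). The 15 genes lower in all treated groups moved the opposite way, with a median of 0.55 (camera, not an exact test, Up, p = 9.52e-05, and p = 0.253 with an estimated correlation). The plantlets of the second experiment differed in age and had 1 library per condition, which keeps this open. A response to NAA that differs with 6-BA, and handling of the NAA libraries, coincide with the groups and were not tested.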

How the results depend on the processing

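Alternatives described as added in the processing section were chosen only after the results were seen. Gene calls with NAA (434) numbered 784 by DESeq2, 246 with only the 4 libraries compared and 131 with a log2 fold change of at least 1, and 112 to 487 without each library in turn. For 6-BA (1420) they numbered 1757 with only the 4 libraries compared, 491 with that fold change and 494 to 1688 without each library, and for both hormones (1374) 1476, 453 and 569 to 1651. Averaged over NAA, 6-BA calls (2582) numbered 457 with the fold change and 1526 to 2409 without each library. For NAA averaged over 6-BA (0) they numbered 214 by DESeq2 and 0 to 1 without each library. Interaction calls (101) numbered 154 with no low-count filter, 383 by DESeq2, 43 and 47 by limma on FPKM plus 1 and plus 0.1, 64 with the fold change and 0 to 204 without each library. For 6-BA added to NAA (1083) calls numbered 1750 by DESeq2 and 387 to 1174 without each library, and for NAA added to 6-BA (0) 40 and 0 to 11. In the second experiment DESeq2 called 6 genes for any dose, 5 for the slope and 82 for week, and with the cell division level as covariate edgeR called 1 for any dose and 2 for week. A stricter threshold lowers counts by construction. For the other changes the cause was not tested.

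The labels do not say that equal replicate numbers share a block, and the pairing correlations between groups ran from -0.15 to 0.21. With the replicate number as a block 351 genes passed for NAA, 1170 for 6-BA, 1123 for both, 2010 for 6-BA averaged over NAA and 37 for the interaction.

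Of 234 pairs of list and contrast 55 passed by camera, 0 with an estimated correlation, 14 by fry and 43 to 63 without each library. Without the 2-week library at 2.0 mg/L, the dose slopes of cell wall loosening and hydrolysis (adjusted p = 0.772), photosynthesis (adjusted p = 0.82) and phenylpropanoid and lignin genes (adjusted p = 0.255) changed direction, and the cause was not tested. The lowest values of these lists were 2.76e-06, 9.83e-12 and 0.0122, without the 4-week library at 2.0 mg/L for the first 2 lists and without the one at 0 mg/L for the last. For the 6-BA genes of the first experiment in the second, the higher set had p = 0.00856 (camera, not an exact test) with a fold change of at least 1, and 0.0693 to 0.505 without each library. The lower set had 0.014 to 0.766 by the same model-based, not exact, test, with a changed direction without the 4-week library at 0 mg/L (p = 0.0903). Calls under alternatives were followed for 99 pairs of named gene and contrast. Of their 1660 values 1482 kept their side of the threshold, 175 lost it, 3 gained it and 0 changed direction. These genes were named for large or low-p changes in the main fit, so their kept directions are little support. The other named genes were not followed this way. They include all values of 6-BA added to NAA, most genes named for 6-BA averaged over NAA, and the genes under other observations.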

Other observations

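The following genes of other pathways were past the threshold for 6-BA averaged over NAA (edgeR's quasi-likelihood test). Their calls were not followed under the alternatives or without single libraries. FLOWERING LOCUS T (LOC110113965), the mobile signal that starts flowering, rose by 3.93 (SE 0.86, adjusted p = 0.016), and the MADS-box gene AGL9 homolog (LOC110114689), a floral organ regulator, rose by 2.42 (SE 0.44, adjusted p = 0.00688), within a floral list of 3 higher and 3 lower of 44. In nitrogen uptake, the transporter NRT1/PTR 5.10 (LOC110092408) fell by 1.44 (SE 0.10) and glutamine synthetase (LOC110103120), which assimilates ammonium, fell by 0.81 (SE 0.08), in a list of 4 higher and 9 lower of 67.

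In phenolic metabolism, caffeoylshikimate esterase-like (LOC110098237), a lignin enzyme, fell by 2.34 (SE 0.24) and laccase-3 (LOC110101486), which polymerises lignin, fell by 0.76 (SE 0.08), in a list of 7 higher and 10 lower of 71. Flavanone 3-dioxygenase 2-like (LOC114580551) fell by 4.06 (SE 0.27), although the flavonoid list had 12 higher and 5 lower of 54. Terpene synthase 10-like (LOC110092385) fell by 0.88 (SE 0.14), in a list of 0 higher and 5 lower of 42. Cyclin-D4-1 (LOC110115423), which drives entry into the cell cycle, fell by 0.91 (SE 0.14), in a cell division list of 2 higher and 3 lower of 65 with a median of 0.07 (camera, Up, adjusted p = 0.49).

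The tests of dose, lectin share, young tissue and depth below were chosen only after the results were seen, and the splits of libraries were planned before. Cell division and histone levels differed between libraries of the second experiment. A dose effect remained open (exact p = 0.62 over 576 orders within times). Lectin genes taking a large share of the counts were excluded, since 2.2% of the range of the cell division level was lost without them. A different share of young tissue in each library remained open, and the shoot meristem list lay on the same side as cell division in 8 of 8 libraries, which could also follow from a hormone effect on growth.

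Genes were taken as strongly changed where both 6-BA against water and 6-BA added to NAA were past the threshold with a change of at least 1 on the log2 scale in that direction. Those strongly lower with 6-BA in the first experiment (169 genes, 113 tested in the second) had lower mean levels at higher doses after 2 weeks, at 0.61, 0.58, -0.12 and -0.37 (slope -0.54, exact p = 0.0417). With 24 orders of the doses, that exact p is the smallest this test of single libraries can give. After 4 weeks they were at -0.21, -0.10, 0.05 and -0.44 (slope -0.12, exact p = 0.5). The genes strongly higher with 6-BA in the first experiment (51 genes, 47 tested) had a negative slope after 2 weeks too (-0.30, exact p = 0.25) and a positive one after 4 weeks (0.13, exact p = 0.542). The 2-week libraries at 1.0 and 2.0 mg/L, where the lower set was low, also had low cell division levels (-0.91 and -1.00) and lay apart on the first principal component (-65.6 and -87.6, against 33.3 and 69.1). That split of the libraries was not tested as an explanation of the set. A dose effect remained open, with an exact p of 0.0399 for the slope over both times and an adjusted exact p of 0.399 over 10 relations. A difference in depth was excluded, with a ratio of 1.05 between the deepest and shallowest 2-week libraries.

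Splits of the 8 libraries into 4 and 4 were counted together with the real grouping. For 6-BA averaged over NAA 1 of 34 splits, the real one, had as many calls as its 2582, and the highest other count was 0. The other splits mixed libraries with and without 6-BA, so any 6-BA difference entered their spread and lowered their counts. A cause shared by the libraries of a group, such as a common harvest, could give the same result. For NAA averaged over 6-BA and for 4 against 2 weeks the real count was 0, which each of the 34 and 35 splits reaches whatever the data, so these counts decide nothing. The highest other counts were 1 for NAA and 3068 for week, the latter for a split that parts the libraries by their cell division level.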
